A study of Mus musculus with 12 samples.

How the data were processed

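RNA from the livers of male C3H/HeN mice of the F2 generation, aged about 74 weeks, was hybridised to 12 Agilent 1-colour (Cy3) whole-genome mouse arrays. Per the labels, F0 dams of the exposed line drank water with 85 ppm sodium arsenite from gestation day 8 to 18, and F1 mice were mated at 10 weeks. Arsenite water was thus given to the F0 dams alone, while they carried the F1 generation. The arrays fall into 4 groups of 3: non-tumour liver of the control line, normal liver of the arsenite line, non-tumour liver of the arsenite line and tumours of the arsenite line. The labels number the samples of a group 1 to 3, and the p-values measure the spread between these numbered samples. Other groups that the study's description names were not analysed here.

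Per the file headers, the deposited scanner files give for each spot a processed signal, an intensity in arbitrary units after background subtraction and spatial detrending, not scaled between arrays. Per the labels, the authors purified RNA on columns with a DNase step, checked it on a Bioanalyzer and labelled 100 ng with a low-input 1-colour kit. The headers name 10.7.3.1 as the scanner software, whereas the authors' processing notes name 12.0.3.1. The deposited value table of the authors holds a ratio on the linear scale: it was checked to be the processed signal divided by the 75th percentile over all spots of that array, with no centring on a reference sample. Fits used the processed signals, and the value table served as an alternative.

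Each array held 59305 spots outside the 3671 control spots, which made up 55681 probes. The log2 of the processed signal minus the array's 75th percentile over non-control spots was used. Spots of a probe were averaged on the log2 scale, leaving out those with an outlier mark. A probe was kept when its signal was well above background on all 3 arrays of at least 1 group, which 24144 probes met. Probes took the symbol of their accession in the reference table (27309 probes), their own symbol (3535) or a synonym (551), and 24286 kept the name in the file. The probe with the highest mean stood for each gene, giving 18100 genes tested. Of these, 4507 had several probes. Genomic positions come from the array annotation on mm9.

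Genes were compared with limma 3.58.1 in R 4.3.3 (2-sided moderated test, default eBayes) in a single fit of the 12 arrays with 1 mean per group, and p was adjusted by Benjamini-Hochberg over all genes tested of a comparison. A gene is called changed when its adjusted p is under 0.05. Differences are on the log2 scale with the standard error (SE) of the fit. The fit pools the spread of a gene over all groups, tumours included. The SE and p of comparisons without tumours therefore also rest on the spread between tumours. Where no array of the lower group was well above background, the fold is a lower bound. For it, each signal of the lower group was raised at least to the dimmest signal still well above background on its own array, and the fold is given as "at least". Where neither group was above background no fold is given. Gene lists were compared with the other genes tested by camera (limma), with a preset correlation of 0.01 and, beside it, a correlation estimated from the residuals, and p was adjusted over the 37 lists of a comparison. Scores of a list per array are medians over its members of the log2 value minus the member's mean over the 9 arrays outside tumours. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

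Before the data were examined, the groups, the 4 comparisons, the 37 gene lists, the rule for named genes and the alternatives were fixed, except where stated. The lists hold 585 genes, of which 9 had no probe. By the rule, the text could name for each comparison the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap and which were well above background in the higher group. It could also name up to 4 called members with the smallest p of each list past the threshold and, where fewer than 5 genes were called, the 5 with the smallest p. Afp, H19, Igf2, Gpc3, Glul, Mki67, Cd74, Tmem54, Dmbt1 and Fabp4 were always included in the tumour comparisons, and Dnmt1, Mt1, Mt2 and Hmox1 in all. Cd74, Tmem54, Dmbt1 and Fabp4 form a list chosen from memory of related work, which may itself have been chosen on these samples. Some genes that the rule names are not reported here.

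The labels do not say whether equal numbers mark the same mouse. Residuals of equal numbers in tumour and non-tumour arrays correlated at 0.15, 0.14 and 0.23, against -0.16 to -0.00 for unequal numbers, which met the rule set for paired samples. A fit of the 6 arrays of that comparison with the number as a block is therefore given beside its results where it changes a call. No other comparison met the rule, though in arsenite non-tumour against normal equal numbers gave 0.07, 0.12 and 0.06, against -0.09 to 0.01 for unequal numbers. Equal numbers also lay in the same column of their slides. These correlations therefore cannot tell a shared mouse from a shared position. The arrays lie on 3 slides: slide 1 holds both non-tumour groups, slide 2 the normal group and slide 3 the tumours. Slide and group therefore coincide in the 3 comparisons within the arsenite line, where spike-in transcripts served as a check, and no fit with slide as a fixed or random term was run.

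On each array 40.5% to 46.9% of spots were well above background, and no spot was saturated (0 spots). The ratio of median signal to background was 2.49 to 2.65 on tumour arrays and 1.39 to 1.61 on the others. The number of arrays limits the precision. Tested on simulated data with 18100 genes, of which 50 changed at each size, the fit of tumour against non-tumour recovered 36% of 1.5-fold, 74% of 2-fold, 94% of 4-fold and 94% of 8-fold changes with 7 false calls. Arsenite non-tumour against normal gave 54%, 78%, 88% and 100%. Each comparison had 1 run, drawn from the same means and spread per gene, so these shares differ by the random draw. Each run also raised the genes of a made-up list. Recovery with far more or far fewer changed genes was not simulated. Alternatives were quantile normalisation, normexp background correction with an offset of 50, a median shift, the authors' value table, no filter, a filter on all arrays, all probes, limma with trend and robust settings, array weights, fits of 6 arrays, fits with a block, and leaving out each array. A scaling on the 75th percentile of probes well above background on all 12 arrays was chosen after seeing the data. Control non-tumour and arsenite normal liver differ in both exposure and tissue and were not compared.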

Results

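Expression was measured on 12 arrays, 3 in each of 4 groups: tumours, non-tumour liver and normal liver of F2 males whose F0 grandmothers drank arsenite in pregnancy, and non-tumour liver of F2 males of the control line. Over the 18100 genes tested, most of the spread lay between tumours and all other arrays. Log2 values of a tumour and another array correlated at 0.905 to 0.934 across genes, those of arrays outside tumours with each other at 0.986 to 0.993, and those of the tumours with each other at 0.982 to 0.987. These are correlations across genes, which are not independent replicates.

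**Figure D1:**
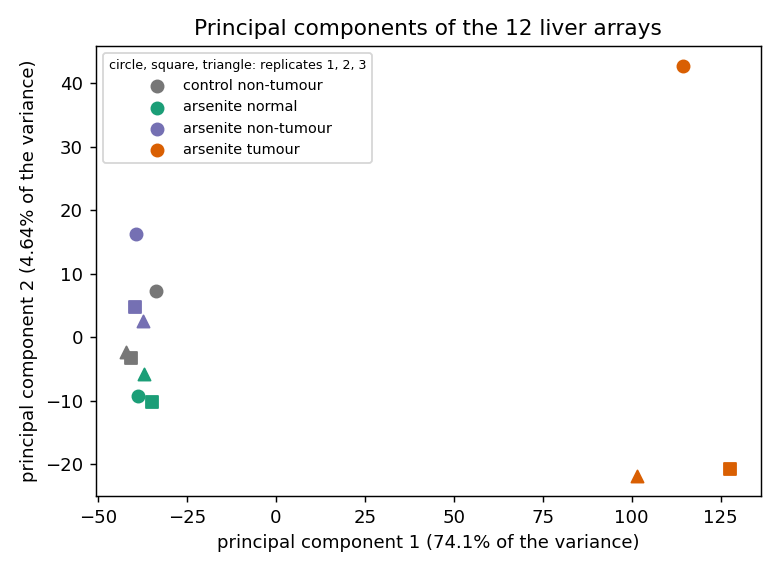
Principal components of the log2 values of the 12 arrays, with component 1 (74.1% of the variance) on the x axis, component 2 (4.64%) on the y axis, and 1 point per array coloured by group. Tumours lie at 101 to 128 on component 1 and the other arrays at -42.1 to -33.6.

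Tumours of the arsenite line were first compared with non-tumour liver of the same line, which asks how tumours differ from non-tumour liver of the same exposure. Most of the tested liver tumour markers rose. Afp, the fetal serum protein on chromosome 5 (mm9, probe 90937781 to 90937840), was at least 2005-fold higher (log2 mean 7.89 ± 1.17 against -3.30 ± 0.14, SD, n = 3 each, adjusted p = 1.7e-07). H19, an imprinted fetal RNA on chromosome 7 (probe 149761492 to 149761551), was at least 840-fold higher, and Gpc3, a cell-surface proteoglycan, at least 243-fold. The tested genes of male-biased liver expression fell, among them the steroid enzyme Hsd3b5 on chromosome 3 (probe 98422576 to 98422635), with a log2 difference of -6.65 ± 0.86 (SE, n = 3 per group, adjusted p = 0.00013). In all 8526 of 18100 genes were called, 3100 higher and 5426 lower, and 3273 differed by at least 2-fold, 1633 higher and 1640 lower. The groups did not overlap in 56.5% of genes tested, where chance gives 10%.

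Of 17 tested liver tumour markers, 15 rose and 1 fell (list adjusted p = 2.2e-12, and adjusted p = 0.0022 with an estimated correlation). Besides Afp, H19 and Gpc3, these included Akr1c18, a progesterone-metabolising enzyme, at 9.75 ± 0.35 (SE, n = 3 per group, adjusted p = 3.2e-08), the stem-cell marker Prom1 at 6.61 ± 0.28 and the Golgi protein Golm1 at 5.38 ± 0.12. The trefoil peptide Tff3 rose by 9.69 ± 0.77, Ly6d by 9.47 ± 0.58 and the desaturase Scd2 by 6.51 ± 0.19. Tert fell by 0.89, and was named after its value was seen. Outside the lists, the largest rises included Erich4 (at least 254-fold), Gldn (at least 171-fold), the leukotriene enzyme Alox5 (at least 157-fold), the kinesin Kif5c (at least 135-fold) and the protease inhibitor Slpi (469-fold). Of 9 imprinted genes tested 3 rose, H19, Igf2r at 1.19 ± 0.13 and Peg3 at least 2.80-fold (list adjusted p = 0.0086, and adjusted p = 0.18 with an estimated correlation). H19 and Peg3 belong to both lists. Igf2 had no probe past the filter. The counts adjusted over the list alone were the same: 15 and 1 for tumour markers and 3 for imprinted genes.

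Cell cycle genes rose in 22 of 25 cases (list adjusted p = 7.9e-11, and adjusted p = 0.27 with an estimated correlation). The proliferation marker Mki67 rose by 3.67 ± 0.40 (SE, n = 3 per group, 12.7-fold, adjusted p = 4.5e-05), the mitotic kinase Plk1 by 4.21 ± 0.46 and the cyclin Ccne1 by 4.16 ± 0.35. Among 15 targets of p53, the damage-response transcription factor, 10 rose and 1 fell (list adjusted p = 2.8e-05, and adjusted p = 0.21 with an estimated correlation), with Phlda3 up by 4.56 ± 0.32, the death receptor Tnfrsf10b by 4.35 ± 0.48 and the apoptosis gene Bax by 1.21 ± 0.09. Of 12 genes switched on by RAS and MAP kinase signalling 10 rose (list adjusted p = 2.2e-06, and adjusted p = 0.026 with an estimated correlation). They included Dusp5, at least 4.09-fold, the feedback inhibitor Spry1 at 2.65 ± 0.29 and the cyclin Ccnd1 at 2.60 ± 0.29. Of 14 immediate early genes 9 rose (list adjusted p = 0.00036, and adjusted p = 0.27 with an estimated correlation), with Egr1 at 5.97 ± 0.48, Btg2 at 4.26 ± 0.23 and Fos at least 4.64-fold. Adjusted over the list alone, the counts were 22 for the cell cycle, 11 and 1 for p53 targets, 10 for RAS output, and 10 higher and 1 lower for immediate early genes.

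Enzymes of urea and amino acid metabolism fell in 21 of 24 cases and rose in 0 (list adjusted p = 1.1e-06, and adjusted p = 0.38 with an estimated correlation). The tyrosine-degrading enzyme Hpd changed by -3.36 ± 0.22 (SE, n = 3 per group, adjusted p = 1.5e-06), Cth by -2.74 ± 0.24 and the methionine enzyme Mat1a by -2.17 ± 0.22. Of 15 bile acid genes 12 fell (list adjusted p = 0.00026, and adjusted p = 0.19 with an estimated correlation), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -6.07 ± 1.17, Cyp8b1 by -5.52 ± 0.50 and the bile acid receptor Nr1h4 by -1.60 ± 0.14. Fatty acid oxidation had 16 lower and 2 higher genes of 24 (list adjusted p = 0.00043, and adjusted p = 0.21 with an estimated correlation), with Cpt2 at -1.63 ± 0.10 and Acaa1b at -2.11 ± 0.18. Of 14 drug-metabolism genes 8 fell (list adjusted p = 0.0044, and adjusted p = 0.37 with an estimated correlation), with Cyp2c29 at -3.66 ± 0.19 and the receptor Nr1i3 at -3.31 ± 0.36. Plasma proteins had 12 lower and 1 higher of 24, with C9 at -2.24 ± 0.20 and Apoa1 at 1.17 ± 0.17 (list adjusted p = 0.040, and adjusted p = 0.78 with an estimated correlation). That list lost its call under quantile normalisation (0.73), normexp (0.17), a median shift (0.063), the block on 6 arrays (0.075), and without non-tumour 1 (0.091), non-tumour 2 (0.057) or tumour 1 (0.10). For these 5 lists, in the order given, the counts adjusted over the list alone were 22 lower, 12 lower, 17 lower and 2 higher, 9 lower, and 13 lower and 1 higher.

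Cholesterol synthesis had 17 higher and 2 lower genes of 23 (list adjusted p = 2.5e-05, and adjusted p = 0.55 with an estimated correlation). Against normal liver of the arsenite line the tumours had 3 higher and 3 lower, and the list did not pass (list adjusted p = 0.087). Its median in non-tumour minus normal liver was -0.90, so the rise depends on the liver that tumours are compared with. Lss rose by 2.81 ± 0.44 (SE, n = 3 per group, adjusted p = 0.00048) and Mvk by 1.31 ± 0.27. In lipid storage 7 rose and 2 fell of 13: the lipid-droplet genes Cidea (at least 104-fold) and Cidec (4.37 ± 0.44) were higher, and Plin5 at -1.84 ± 0.20 was lower (list adjusted p = 0.027, and adjusted p = 0.27 with an estimated correlation). That call was lost under quantile normalisation (0.071), with the block on 6 arrays (0.066), without non-tumour 1 (0.058) and without tumour 1 (0.063). Of the list chosen from memory of related work, which is not independent evidence of its direction, 2 of 3 tested genes rose, Tmem54 at 4.99 ± 0.43 and Fabp4 at 1.75 ± 0.17 (list adjusted p = 0.016, and adjusted p = 0.19 with an estimated correlation). Cd74 was at 0.35 ± 0.26 (adjusted p = 0.29), and Dmbt1 had no probe past the filter. With p adjusted over the list alone, cholesterol synthesis had 18 higher and 2 lower, lipid storage 7 and 2, and the third list 2 higher.

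All 10 tested genes of male-biased liver expression fell (list adjusted p = 0.00013, and adjusted p = 0.28 with an estimated correlation). Besides Hsd3b5 they included the transporter Slco1a1 at -6.23 ± 0.57 (SE, n = 3 per group, adjusted p = 1.4e-05), Cyp4a12a at -5.48 ± 0.55 and Ugt2b1 at -3.93 ± 0.29. Of 8 female-biased genes 4 rose (list adjusted p = 0.030, and adjusted p = 0.37 with an estimated correlation), including Sult2a2, at least 123-fold, and Cyp2a4 at 1.87 ± 0.34. That list lost its call under quantile normalisation (0.061), without non-tumour 1 (0.058) and without non-tumour 2 (0.070), and Hao2, at 3.14 ± 0.79, lost its own with the block on 6 arrays (0.080). Cyp2b13, well above background on 1 of 3 non-tumour arrays, rose (adjusted p = 0.028) but lost its call with no filter (0.054), in the fit of 6 arrays (0.068), and without non-tumour 1 (0.11), non-tumour 2 (0.086), tumour 2 (0.076) or tumour 3 (0.084). The largest falls outside the lists were those of the developmental transcription factor Pax2 (-9.06 ± 0.62, chromosome 19, probe 44909895 to 44909954), Lrtm1 (-7.43 ± 0.55) and the pigment enzyme Dct (-7.10 ± 0.97). Counts adjusted over the list alone were 10 male-biased genes lower and 4 female-biased genes higher.

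**Figure D2:**
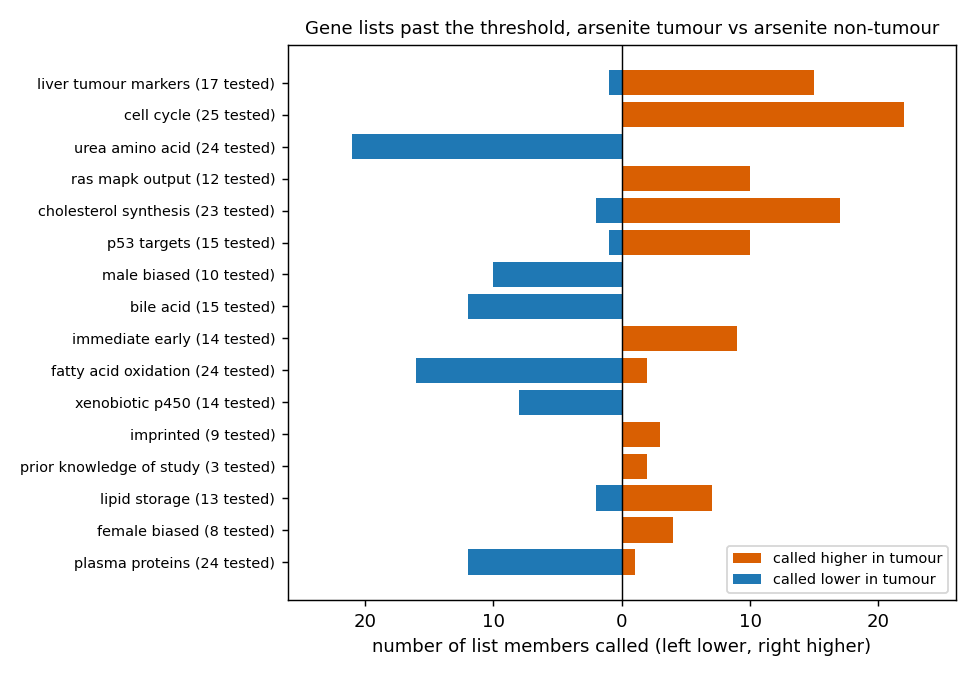
Numbers of called genes (x axis) that were higher or lower in arsenite tumours than in arsenite non-tumour liver, for the 16 gene lists past the threshold (y axis). Bars count members, for example 22 higher for the cell cycle and 21 lower for urea and amino acid metabolism.

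Markers of the liver lobule's zones differed between tumours. Among 17 genes of the pericentral zone 7 fell and 1 rose, and among 15 of the periportal zone 8 fell and 1 rose, and neither list passed (adjusted p = 0.084 and 0.11). Without tumour 1 the pericentral list passed at 1.9e-06, as it did under a median shift with all arrays (0.046), and without tumour 3 the periportal list passed at 0.011. With all arrays, each list had adjusted p = 0.79 with an estimated correlation. The glutamine synthetase gene Glul, a pericentral marker on chromosome 1 (probe 155756765 to 155756824), had a log2 value of 6.25 in tumour 1, 0.41 in tumour 2 and 1.80 in tumour 3, against 5.56 ± 0.21 (SD, n = 3) in non-tumour liver. Its difference of -2.74 ± 1.10 did not pass (adjusted p = 0.064). It passed without tumour 1 (8.5e-06) and with array weights (0.0071).

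**Figure D3:**
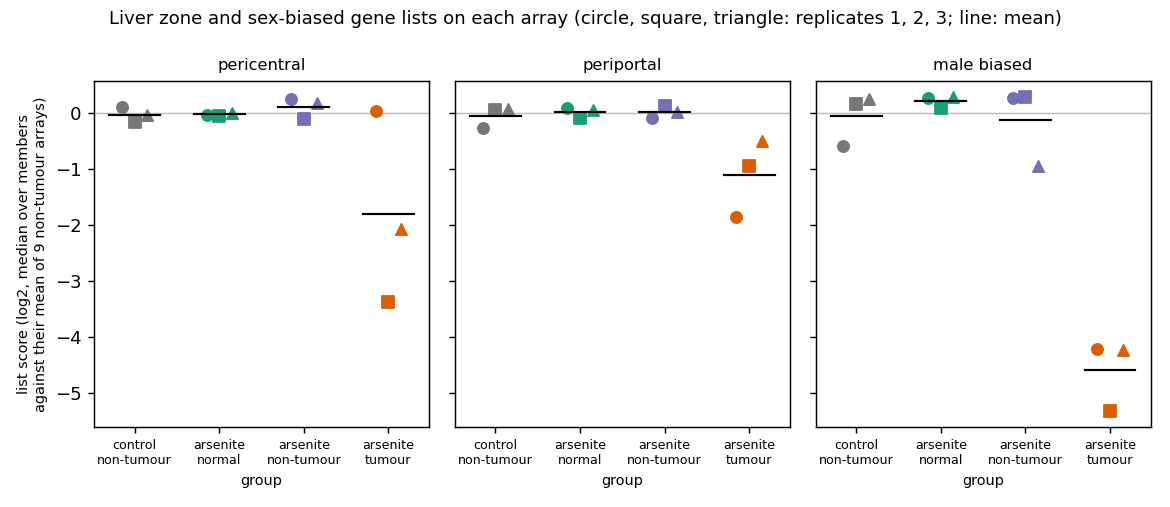
Scores (y axis, log2) of pericentral, periportal and male-biased genes on each of the 12 arrays, by group on the x axis, with circle, square and triangle for samples 1, 2 and 3 and a line at the group mean. Pericentral scores are 0.04, -3.37 and -2.07 in the tumours, and male-biased scores -4.20, -5.31 and -4.22.

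Other cell types moved unevenly. Macrophage markers had 11 lower and 1 higher of 15, with a median of -0.87, and did not pass (adjusted p = 0.051, and adjusted p = 0.75 with an estimated correlation). They passed with the block on 6 arrays (0.0098), under quantile normalisation (0.039), normexp (0.034) and a median shift (0.038), and without non-tumour 2 (0.025), tumour 1 (0.027) or tumour 3 (0.049). Endothelial markers had 4 higher and 5 lower of 19 (0.69, median -0.02, mean 0.14), stellate cell and fibroblast markers 5 higher and 7 lower of 14 (0.85), bile duct markers 2 higher of 7 (0.12), T and NK cell markers 2 higher and 1 lower of 11 (0.15), and B and plasma cell markers 2 higher of 6 (0.10). Interferon-induced genes had 3 higher of 25 (0.15) and passed without non-tumour 3 (0.00088) or without tumour 2 (0.020), and MHC class II genes had 1 higher of 8 (0.26). Among genes tied to arsenic or methylation, Hmox1, which responds to oxidative stress, changed by -0.86 ± 0.21 (adjusted p = 0.0065, and 0.056 with the block on 6 arrays). The metallothioneins Mt1 (-0.61 ± 1.03, 0.66) and Mt2 (-2.0 ± 1.23, 0.21, and 0.019 with the block on 6 arrays) and the methyltransferase Dnmt1 (0.11 ± 0.10, 0.37) did not pass. The block on all 12 arrays did not change the call of Hao2, Hmox1 or Mt2.

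The balance of rises and falls depended on the scaling: 36.4% of called genes were higher, against 47.8% after quantile normalisation and 53.5% with the percentile of detected probes, chosen after seeing the data. Tumours lay on a slide of their own. Bright spike-in transcripts departed from their median by at most 0.296 (log2) between these groups. Slide and group cannot be told apart for dim probes, for differences near that size or for slide effects on single probes. Of the 16 lists past the threshold, tumour markers and RAS output alone held with an estimated correlation. That loss of calls does not reflect correlation between genes alone. Imprinted genes had an estimated correlation of 0.00118, below the preset 0.01, and still went from an adjusted p of 0.0086 to 0.18 in camera.

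The tumours were also compared with normal liver of the arsenite line. Liver tumour markers and cell cycle genes were again higher and male-biased genes lower. Prom1 rose by 7.5 ± 0.28 (SE, n = 3 per group, adjusted p = 4.7e-08), the tetraspanin Tspan8 by 8.44 ± 0.28 and Mki67 by 4.20 ± 0.40, and H19 was at least 723-fold and Gpc3 at least 214-fold higher. Pax2 changed by -9.50 ± 0.62, Hsd3b5 by -7.25 ± 0.86 and the glycine methyltransferase Gnmt by -3.21 ± 0.34. In all 8710 genes were called, 3107 higher and 5603 lower, and 3256 by at least 2-fold (1592 higher, 1664 lower). The groups did not overlap in 58.8% of genes, where chance gives 10%. Both tumour comparisons called 2626 genes higher and 4723 lower, and 0 in opposite directions, where independent lists would share 532.1 and 1679.7. They use the same tumour arrays, so part of the excess may come from that. Their differences correlated at 0.968 across genes. Simulations with only the shared arrays in common gave 0.50, which their setup fixes whatever the data. That value therefore does not measure how much of the overlap the shared arrays add.

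Of 17 tested tumour markers 15 rose and 1 fell (list adjusted p = 1.3e-12, and adjusted p = 0.0021 with an estimated correlation), and of 25 cell cycle genes 22 rose (2.0e-12, and adjusted p = 0.22 with an estimated correlation). RAS output rose in 9 of 12 genes (1.4e-05, and adjusted p = 0.040 with an estimated correlation), with Etv5 at 1.17 ± 0.16 (SE, n = 3 per group). The p53 targets rose in 10 of 15 (4.0e-05, and adjusted p = 0.22 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 3.68 ± 0.43. Imprinted genes rose in 4 of 9 (0.0078, and adjusted p = 0.13 with an estimated correlation), among them Mest at 0.94 ± 0.14, and female-biased genes in 5 of 8 (0.012, and adjusted p = 0.38 with an estimated correlation). Immediate early genes had 6 higher and 1 lower of 14 (0.010, and adjusted p = 0.41 with an estimated correlation): Egr1 rose by 3.13 ± 0.48 and the phosphatase Dusp1 changed by -1.58 ± 0.23. With p adjusted over the list alone, 23 cell cycle genes rose and the counts of the other 6 lists stayed as given.

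Lists with mostly lower members were urea and amino acid metabolism with 19 lower of 24 (5.7e-06, and adjusted p = 0.41 with an estimated correlation), bile acids with 12 of 15 (0.00015, and adjusted p = 0.16 with an estimated correlation) and male-biased genes with 10 of 10 (7.0e-05, and adjusted p = 0.28 with an estimated correlation). Fatty acid oxidation had 16 lower and 2 higher of 24 (0.0027, and adjusted p = 0.24 with an estimated correlation), and drug metabolism 9 lower of 14 (0.0071, and adjusted p = 0.41 with an estimated correlation). Plasma proteins had 13 lower and 1 higher of 24 (0.022, and adjusted p = 0.69 with an estimated correlation). That call was lost under quantile normalisation (0.83), normexp (0.19), a median shift (0.11), without normal 1 (0.059) and without tumour 1 (0.060). Lipid storage had 7 higher and 2 lower of 13 (0.010, and adjusted p = 0.22 with an estimated correlation), and lost its call under a median shift (0.059). When adjusted over the list alone, urea and amino acid metabolism had 20 lower and fatty acid oxidation 17, and the other counts stayed as given.

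Of 8 MHC class II genes 6 rose (list adjusted p = 0.0041, and adjusted p = 0.41 with an estimated correlation), with H2-Eb1 at 1.52 ± 0.28 (SE, n = 3 per group), H2-Ab1 at 1.29 ± 0.23 and Cd74, the invariant chain, at 1.06 ± 0.26 (adjusted p = 0.0062). Macrophage markers had 7 lower and 1 higher of 15, with a median of -0.70, and did not pass (0.15, and adjusted p = 0.76 with an estimated correlation), but did under a median shift (0.023) and with the block on 6 arrays (0.021). T and NK cell markers had 2 higher and 1 lower of 11 (0.16, and 0.048 with the block on 6 arrays), B and plasma cell markers 2 higher of 6 (0.25), endothelial markers 5 higher and 4 lower of 19 (0.32), stellate cell and fibroblast markers 3 higher and 7 lower of 14 (0.56), and bile duct markers 2 higher of 7 (0.092, and 0.042 without tumour 1). Of 25 interferon-induced genes 3 rose (0.021, and adjusted p = 0.76 with an estimated correlation), with the chemokine Cxcl10 at 2.62 ± 0.48 and the antiviral gene Oas1a at 1.90 ± 0.60. The interferon call was lost under quantile normalisation (0.082), a median shift (0.098), without normal 2 (0.081) and without tumour 3 (0.33), and Oas1a lost its own without normal 2 or tumour 3 (0.088 each). The list chosen from memory of related work, not independent evidence, had 3 higher of 3 (0.0060, and adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis had 3 higher and 3 lower of 23 and did not pass (0.087), though it did under normexp (0.024), with the block on 6 arrays (0.0020) and without normal 2 (0.034). The pericentral list had 9 lower and 1 higher of 17 (0.094, with 0.0028 under a median shift and 2.4e-06 without tumour 1), and the periportal list 8 lower and 1 higher of 15 (0.15, with 0.011 under a median shift and 0.016 without tumour 3), and both had adjusted p = 0.76 with an estimated correlation. Glul was at -2.73 ± 1.10 (0.064, with 0.0047 with array weights and 9.4e-06 without tumour 1), Dnmt1 at 0.13 ± 0.10 (0.29), Mt1 at 0.20 ± 1.03 and Mt2 at -0.25 ± 1.23. Hmox1, at -0.66 ± 0.21 (0.023), lost its call in 9 settings, with 0.051 to 0.15, among them those without normal 1 (0.054), normal 2 (0.059), normal 3 (0.051) and tumour 2 (0.068). Counts adjusted over the list alone were 2 higher for interferon-induced genes and 1 higher and 2 lower for cholesterol synthesis. They were 6 higher and 7 lower for endothelial markers, 4 higher and 7 lower for stellate cell and fibroblast markers, and as given for the other lists.

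The share of called genes that were higher was 35.7%, against 48.3% after quantile normalisation, 62.0% with a median shift and 50.6% with the percentile of detected probes, chosen after seeing the data. Between these slides, bright spike-ins departed by at most 0.173. Here too, dim probes, differences near that size and slide effects on single probes leave slide and group impossible to tell apart.

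Non-tumour liver of the arsenite line was compared with normal liver of the same line. No single gene passed, while 6 of the 37 gene lists did. Genes of cholesterol synthesis were lower in non-tumour liver, with a median difference of -0.90 over 23 genes (list adjusted p = 1.9e-14, and adjusted p = 0.505 with an estimated correlation). MHC class II genes were higher, with a median of 0.69 over 8 genes (4.7e-08, and adjusted p = 0.458 with an estimated correlation), and immediate early genes lower, with a median of -0.53 over 14 (2.3e-05, and adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone, 2 cholesterol genes and 4 immediate early genes were lower and 5 MHC class II genes higher. Macrophage markers, a cell type that presents antigen, were at a median of 0.28 over 15 genes and did not pass (adjusted p = 0.052, and adjusted p = 0.86 with an estimated correlation). They passed under normexp (0.027), with the block on 6 arrays (0.00066), and without normal 1 (0.036), normal 3 (0.0076) or non-tumour 2 (0.0020). Macrophage markers were not alone near the threshold. Interferon-induced genes (median 0.325, adjusted p = 0.052), acute-phase genes (0.325, 0.053) and cell cycle genes (0.12, 0.053) also leaned upward and did not pass. Each had adjusted p = 0.86 with an estimated correlation. With 1 array left out they passed in 3, 1 and 2 of 6 fits.

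limma called 0 genes of 18100, with 1237 at an unadjusted p under 0.05 where chance gives 905. The spread in this fit includes that between tumours. A limma fit of the 6 arrays alone also called 0 genes, with 1589 at an unadjusted p under 0.05. The other settings called 0 to 5, the most with array weights. Fkbp11, at least 1.76-fold lower (adjusted p = 0.18), Mt1 (0.81 ± 1.03, SE, n = 3 per group), Mt2 (1.75 ± 1.23), Hmox1 (0.19 ± 0.21) and Dnmt1 (0.02 ± 0.10) did not pass. Groups did not overlap in 15.2% of genes, where chance gives 10%.

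Fatty acid oxidation was higher by a median of 0.13 (0.021, and adjusted p = 0.56 with an estimated correlation) and lost its call under a median shift (0.16) and without non-tumour 3 (0.35). RAS output was lower by a median of -0.20 (0.021, and adjusted p = 0.458 with an estimated correlation), and lost its call under quantile normalisation (0.065) and without non-tumour 1 (0.091). Lipogenesis was lower by a median of -0.24 (0.025, and adjusted p = 0.86 with an estimated correlation), and lost its call under normexp (0.092) and without normal 1 (0.17), normal 2 (0.26), non-tumour 1 (0.61) or non-tumour 3 (0.077). The groups lay on different slides, between which bright spike-ins departed by at most 0.133. For dim probes, for differences near that size and for slide effects on single probes, slide and group cannot be told apart.

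**Figure D4:**
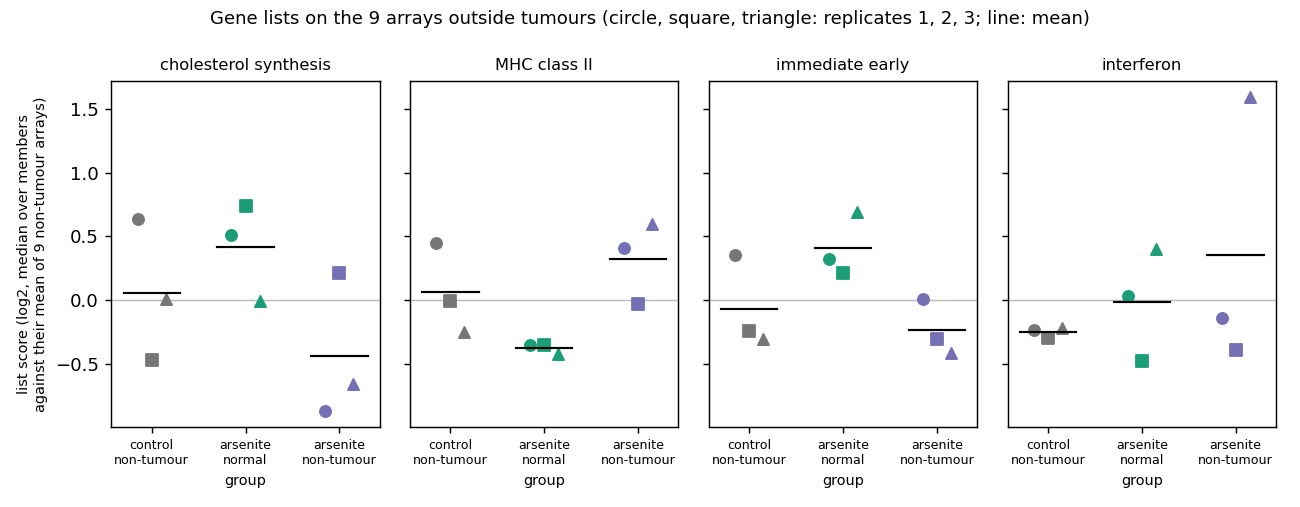
Scores (y axis, log2) of cholesterol synthesis, MHC class II, immediate early and interferon-induced genes on the 9 arrays outside tumours, by group on the x axis, with circle, square and triangle for samples 1, 2 and 3 and a line at the group mean. MHC class II scores are -0.36, -0.35 and -0.42 in normal liver and 0.41, -0.03 and 0.60 in arsenite non-tumour liver.

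Non-tumour liver of the arsenite line was compared with that of the control line, which asks whether exposure of the F0 dams is seen outside tumours in the liver of their grandoffspring. Interferon-induced genes were higher in the arsenite line by a median of 0.65 over 25 genes (list adjusted p = 1.7e-05, and adjusted p = 0.93 with an estimated correlation). That call rested on 1 array: without arsenite non-tumour 3 it was 0.99, and it was 0.13 under a median shift. Cell cycle genes were higher by a median of 0.36 over 25 genes (8.4e-05, and adjusted p = 0.93 with an estimated correlation) and lost their call under normexp (0.26) and a median shift (0.15). Cholesterol synthesis was lower by a median of -0.55 over 23 genes (8.4e-05, and adjusted p = 0.93 with an estimated correlation), and lost its call without control 1 (0.42) or arsenite non-tumour 1 (0.21). Macrophage markers were higher by a median of 0.31 over 15 genes (0.0014, and adjusted p = 0.93 with an estimated correlation), and lost their call under a median shift (0.22) and without control 2 (0.22), control 3 (0.13), arsenite non-tumour 1 (0.061) or 3 (0.092). Adjusted over the list alone, 0 members of these lists were called by limma.

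limma called 1 gene of 18100, with 1019 at an unadjusted p under 0.05 where chance gives 905. This gene, Sh3bp4 on chromosome 1 (probe 91048945 to 91049742, across a junction), was lower in the arsenite line (adjusted p = 0.0097). It was well above background on no array of either group, so no size is given. It was not tested with a filter on all arrays, and it lost its call under normexp, with trend and robust settings, with the block on 6 arrays, and without control 1 or arsenite non-tumour 1 or 3. Dnmt1 (-0.24 ± 0.10, 0.80), Mt1 (-0.41 ± 1.03, SE, n = 3 per group), Mt2 (-0.22 ± 1.23) and Hmox1 (0.17 ± 0.21) did not pass. Groups did not overlap in 10.5% of genes, where chance gives 10%. Both groups lay on slide 1, the control arrays in row 1 and the arsenite arrays in row 2, so row and group cannot be told apart. A fit of these 6 arrays alone called 4 genes.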

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

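The scaling on the percentile of detected probes was chosen after seeing the data; the other alternatives were planned. No named gene that was called turned its direction in any setting, and no called gene list did in the settings run for lists. Those were the estimated correlation, quantile normalisation, normexp, a median shift, the block on 6 arrays and leaving out each array. Lists were not run in the other settings, the percentile of detected probes among them. Among named genes not called, Dnmt1, Mt1 and Mt2 turned in some settings, Dnmt1 from -0.24 to 0.04 under a median shift for arsenite non-tumour against control. Of the checks of named called genes, 1519 kept and 8 lost the call for tumour against non-tumour, and 1569 kept and 14 lost it for tumour against normal. Total counts of called genes stayed within 1.5 times except as follows. For tumour against non-tumour, genes called and at least 2-fold numbered 2010 under normexp and 2154 with a filter on all arrays. For tumour against normal they numbered 1967 and 2117, and 14218 genes were called with no filter, of 34739 then tested. Genes called lower in that comparison, 5603 as reported, numbered 2328 under a median shift and 11138 with no filter. For arsenite non-tumour against normal, a median shift, a filter on all arrays, and trend and robust settings each called 1 gene, array weights 5, and fits without 1 array 0 to 1. For arsenite non-tumour against control, normexp, a filter on all arrays, trend and robust settings and the block on 6 arrays each called 0, a median shift 3, no filter 6, array weights 4, the 6 arrays without a block 4, and fits without 1 array 0 to 3. In these 2 comparisons the counts past the 2-fold limit were the same numbers, and include genes near background for which no size is given. The cause was not tested. Leaving out 1 array gave 7429 to 8050 genes for tumour against non-tumour and 7444 to 8112 for tumour against normal. For tumour against non-tumour, the block on sample number called 8426 genes with all 12 arrays, 8137 of them among the 8526. The 6 arrays of that comparison alone called 7505 without the block (7206 of the 8526) and 7119 with it (6657 of the 8526). Quantile normalisation kept 7501 of those 8526.

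A median shift moved the median difference of all genes from -0.15 to 0.09 (tumour against normal), from -0.00 to 0.32 (non-tumour against normal) and from -0.02 to 0.26 (non-tumour against control), so counts of rises and falls hold relative to the scaling. Genes near background are also limited by their signal: 40.5% to 46.9% of spots were well above background, and tumour arrays had a ratio of signal to background of 2.49 to 2.65 against 1.39 to 1.61 elsewhere. Dnmt1 passed in both tumour comparisons (0.27, adjusted p = 0.041 in each) with the percentile of detected probes alone.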

Other observations

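Of the tests below, the dim spike-in probes, the spike-ins between tumour and normal and between non-tumour and normal arrays, the macrophage markers, the share of zonal genes kept, the feeding score and the clock phase were chosen only after the result was seen. The genes in the next 2 paragraphs belong to lists fixed beforehand, and were picked after their values were seen.

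Several lists that did not pass between arsenite tumours and non-tumour liver had members that moved apart. In the list for stellate cells and fibroblasts, the matrix genes Dcn and Lum changed by -2.05 ± 0.11 and -1.58 ± 0.14 (SE, n = 3 per group) and the retinoid enzyme Lrat by -2.14 ± 0.25, while the collagen Col1a1 rose by 2.11 ± 0.37 and the contractile gene Acta2 by 1.57 ± 0.36. In the acute-phase list (4 higher and 4 lower of 18, list adjusted p = 0.71, median -0.26 and mean -0.21 with the test upward), Lcn2 rose by 5.08 ± 0.69 and Il1rn at least 12.3-fold, while the iron hormone Hamp changed by -3.59 ± 0.49 and Orm3 by -3.82 ± 0.74. Among 23 oxidative stress and metal genes, 5 rose and 10 fell (0.53): G6pdx, the entry enzyme of the pentose phosphate pathway, rose by 3.05 ± 0.18, while the glutathione transferase Gsta2 changed by -5.09 ± 0.21 and the quinone reductase Nqo1 by -2.42. Among 10 DNA methylation genes (0.85), Uhrf1, which recruits Dnmt1, rose by 2.51 ± 0.47, the demethylating enzyme Tet1 changed by -2.58 ± 0.15 and Dnmt3b by -0.98 ± 0.32. Lipogenesis (6 higher and 5 lower of 19, 0.44), glycolysis and hypoxia (6 lower of 16, 0.96), the circadian clock (4 lower of 13, 0.53), ER stress (4 higher and 2 lower of 16, 0.53), and neutrophil (2 lower of 5, 0.74), adipocyte (2 higher of 3, 0.10), erythroid (1 lower of 3, 0.53) and pancreatic (1 higher and 1 lower of 5, 0.58) markers did not pass either.

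Arsenite non-tumour 3 stood apart from the other arrays outside tumours. Its interferon score was 1.60, and that of tumour 3, which has the same number, was 1.35. Its female-biased score was 1.68, against 1.74 to 2.37 in the tumours, and its male-biased score -0.95. Elovl3, a male-biased gene, had a log2 value of 0.79 in it against 5.81 and 5.75 in non-tumour 1 and 2, and the female-biased Cyp2b13 was well above background in it alone of these 3 arrays.

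For the difference between tumours and the other arsenite groups, slide and cell mixture were weighed. Of 10 spike-in transcripts on the arrays, 7 were at least 2 times background. Between tumour and non-tumour arrays these departed from their median by at most 0.296 (log2), with an SD of 0.16. Over all genes tested, dim ones included, the SD was 1.15. Each spike-in value was a mean over 35 spots, whereas the 55681 probes outside the controls had 59305 spots. Spike-ins were also taken as mean signal minus local background, not as the processed signal. For bright probes their small departure argues against a slide or hybridisation effect common to all probes as the source of differences of at least 2-fold. Effects on single probes or spots stay open. Differences near 0.296 or smaller cannot be told apart from slide in this way, and 3273 of the 8526 called genes reached 2-fold. The 3 dim spike-ins departed by up to 2.14, so for dim genes slide and group cannot be told apart. Between tumour and normal arrays the largest departures were 0.173 (bright) and 1.81 (dim). A loss of hepatocytes in favour of every other cell type would raise macrophage markers, which had a median of -0.87. RNA handling before labelling and changes in some cell types stay open, and tumour tissue itself is the untested biological explanation.

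Pericentral genes were high in tumour 1 alone. It kept 110% of the non-tumour level of pericentral genes (median over members), against 8.36% and 20.6% in tumours 2 and 3, and 25.5% of the periportal level, against 53.8% and 74.2%. Adjacent liver taken with tumour 1 would bring male-biased genes along, and it kept 5.58% of those, against 3.64% and 6.36%, which argues against that source. No biological explanation was tested.

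Lower cholesterol synthesis genes in arsenite non-tumour than in normal liver may follow the animals' feeding or time of day. Over the 9 arrays outside tumours, the cholesterol score correlated with the lipogenesis score (Pearson's r = 0.759, exact permutation p = 0.018, Spearman's rho = 0.80, exact p = 0.014, r = 0.707 without the 2 arrays farthest from the median, r = 0.763 with group means removed). It also correlated with clock phase, the mean of Arntl and Clock minus that of Dbp and Nr1d1 (r = -0.705, exact permutation p = 0.036, rho = -0.667, exact p = 0.059, r = -0.522 without the 2 farthest, r = -0.555 with group means removed). These were the 2 relations computed, with adjusted p = 0.036 for each, and on the 6 arrays of slide 1 neither passed (r = 0.66, exact p = 0.15, and r = -0.66, exact p = 0.16), and slide 2 holds 3 arrays of 1 group, so feeding, time of day and tissue stay open. The permutations took all 9 arrays as exchangeable, though they come from 3 groups. A correlation of 2 list scores does not show feeding to be the cause. Clock phase was -3.02, -3.54 and -3.45 in normal and -0.95, -1.53 and -1.93 in arsenite non-tumour liver, with no overlap. The r with group means removed includes the control arrays, which are not part of this comparison. Bright spike-ins departed by at most 0.133 between these slides, against a median of -0.90 ± 0.46 (SD over the 23 genes, all well above background). These values argue against a slide or hybridisation effect common to bright probes.

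Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For tumour against non-tumour, 1 of the 10 splits called as many genes as the real 8526, with 3 in the highest other, and 3 splits passed as many lists as the real 16, with 20 in the highest other. That split, like the real one, parts all 3 number pairs, while 6 of the 10 part 1 pair. For tumour against normal, 1 split called as many as 8710 (highest other 0) and 2 passed as many lists as 17 (highest other 17). For arsenite non-tumour against normal, 10 splits called at least the real 0 (highest other 1, by limma, with 1237 at an unadjusted p under 0.05 in the real one) and 5 passed at least 6 lists (highest other 10). For arsenite non-tumour against control, 2 splits called at least 1 gene (highest other 2) and 9 passed at least 4 lists (highest other 13). Each other split joins 2 arrays of 1 group with 1 of the other, so it still holds part of the group difference. Its list count is therefore no measure of chance. Whether that remainder, a structure of the samples or the preset correlation of 0.01, against estimates of up to 0.838, accounts for lists passing in other splits was not tested.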
